A study of Homo sapiens with 17 samples.

How the data were processed

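Messenger RNA levels were measured by RNA sequencing in 17 libraries of HEK293, a human embryonic kidney cell line, which differed in the genotype of MRPS5, a protein of the small subunit of the mitochondrial ribosome. Per the labels, 7 libraries carried wild-type MRPS5 (WT), 5 carried the G313R substitution and 5 carried the V336Y substitution. Total RNA was extracted from cultured cells with a column kit and made into libraries by a standard Illumina procedure, per the labels' protocols. The labels do not say whether the libraries of a genotype came from separate cultures or clones, so p-values measure the spread between these libraries, which may be partly technical. Replicates were numbered in the order of the records, and the numbers pair no libraries.

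The deposited values were raw read counts per Ensembl gene, 1 column per library. Per the submitters' processing notes, bcl2fastq 1.8.4, STAR 2.4.2a and featureCounts were used on GRCh38. Their roles and order, the annotation release, the strand setting, the treatment of reads shared between genes and the selection of messenger RNA are not given in the sources used here. In the deposited counts every one of the 10119 values of 10000 or more ended in 0, so that large values carried 4 significant digits. The table had 21174 genes, of which 20899 matched GENCODE v29 by identifier and 275 did not. Gene names, GRCh38 positions and gene types were taken from GENCODE v29. Because the strand setting is not known, reads of overlapping genes and antisense partners could be counted together, and such genes are named below as overlapping where they are reported.

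Library totals ran from 21240434 to 56964055 counts, with a mean of 3.83e+07. No pair of libraries of 1 genotype was a duplicate: the chi-square statistic of their counts divided by its degrees of freedom was at least 5.62, where sampling noise alone gives about 1.

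Genes were tested with edgeR 4.0.16 in R 4.3.3. Genes were kept with filterByExpr by genotype, which left 14068. Libraries were scaled with trimmed mean of M values factors, dispersions were estimated with the default settings, and the quasi-likelihood F-test (glmQLFit with robust prior, glmQLFTest) was run on all 17 libraries in 1 fit with a term per genotype and no covariate. The biological coefficient of variation was 18.2%. P-values were adjusted by the Benjamini-Hochberg method over all genes tested in a comparison, with a threshold of 0.05. Standard errors (SE) of log2 fold changes were taken from the fold change and the F statistic. CPM (counts relative to the library total) were scaled with the same factors, and means are given with their SD over libraries.

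Before the data were examined, 41 gene lists with 952 entries were fixed (943 entries had a row), and 39 lists had the 3 or more tested members required. Each was tested with camera (limma 3.58.1) at a preset correlation of 0.01 between genes, with adjustment over the 39 lists. The alternatives were a correlation estimated from the data, the rotation test fry with its directional p, and, added after seeing the data, an exact permutation of the mean log2 CPM of the list over libraries. The share of counts on the 13 mitochondrially encoded mRNAs, library totals, genes detected, the share of mitochondrial rRNA and MRPS5 CPM were compared by two-sided exact permutation tests over all 792 arrangements of 5 in 12 libraries, or 252 of 5 in 10, with adjustment over these measures and comparisons.

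Genes named in the text followed a rule fixed at the same time: MRPS5 always; for each mutant against WT up to 10 higher and 10 lower protein-coding genes with the largest fold change among those past the threshold, at an average log2 CPM of at least 2, with every mutant library beyond every WT library; up to 5 each way for V336Y against G313R; and per described list up to 4 members with the smallest p and, where none passed 0.05, up to 2 with the highest CPM. Genes named outside it are marked as such, and some genes that it selects are not reported here.

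The agreement of the mutants' log2 fold changes against WT was measured as Pearson r and covariance over 14068 genes, which are not independent replicates. Because both share the WT libraries, 20 data sets without any genotype effect were simulated, with all 17 libraries drawn independently. The WT libraries were also divided into 3 and 4 in all 70 ordered ways, with 1 part as control for each mutant.

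Regional levels were medians, per library, of the deviation of each gene from its median over libraries, in 244 windows of 10 Mb with at least 15 genes at a log2 CPM of 3 or more (9558 genes).

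Alternatives to the gene test were DESeq2 1.42.0, limma-voom with quality weights and other scaling (RLE, upper quartile, library totals). Others were other filters (none, or at least 1 CPM in 5 libraries), only the compared groups, a test against a fold of 1.2, and 1 surrogate variable (sva 3.50.0). Each library was left out in turn. Libraries whose title numbers lay apart from others of their genotype were also left out (WT replicates 6 and 7, or G313R replicate 1). G313R replicate 1 had number 240. G313R replicates 2 to 5 had 304 to 307, above the highest number in WT (260) and in V336Y (249). What the numbers stand for is not given. A batch that followed them would be largely confounded with G313R in both comparisons that include it. Added after seeing the data were offsets that removed each library's trend with gene GC content, offsets that removed the median deviation of the 40 nearest other expressed genes, and robust dispersions. Figures were drawn with matplotlib 3.10.9.

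The steps were tested on simulated data. For V336Y against WT, drawn over 14015 genes, 68.7% of genes changed 1.5-fold, 94.0% of those changed 2-fold and 100% of those changed 4-fold were recovered, with 10 unchanged genes called. The figures for G313R against WT, over 14026 genes, were 70.1%, 95.5% and 100%, with 8 unchanged genes called, and for V336Y against G313R, over 14004 genes, 65.7%, 97.0% and 100%, with 8. A list raised 1.2-fold was recovered in each comparison with none of the 38 other lists called. Genes and libraries were drawn independently in these simulations. They do not show how the gene and list tests perform with correlated genes and unequally alike libraries. A shift of 0.5 (log2) given to 1 window was found as 0.486 over 9483 genes, with 0.185 the largest value elsewhere, and a shared covariance of 0.0896 was found as 0.0900 over 14068 genes.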

Results

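The series measured the transcriptome of HEK293 cells with wild-type MRPS5 (WT, 7 libraries), MRPS5 G313R (5 libraries) or MRPS5 V336Y (5 libraries). Total counts were 3.73e+07 ± 7.97e+06 (SD, n = 7) in WT, 3.79e+07 ± 4.86e+06 (n = 5) in G313R and 4.01e+07 ± 1.26e+07 (n = 5) in V336Y, and 16021 ± 207 genes (SD, n = 17) had at least 1 count. The design compares each mutant with WT, which asks how each substitution in this mitochondrial ribosomal protein alters mRNA levels, and the mutants with each other.

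MRPS5 itself (ENSG00000144029, chromosome 2, 95087207 to 95149434 on GRCh38, minus strand) varied widely within each genotype. Its level was 851 ± 445 CPM (SD, n = 7) in WT, 546 ± 276 CPM (n = 5) in G313R and 674 ± 202 CPM (n = 5) in V336Y, and single libraries ranged from 230 CPM (G313R replicate 1) to 1642 CPM (WT replicate 3). In each library it stood 3.37 to 22.8 times above the median of the other small-subunit mitoribosome mRNAs, which was 68.2 ± 6.18 CPM over the 17 libraries. The log2 fold change was -0.34 ± 0.36 (SE) in V336Y and -0.64 ± 0.37 in G313R against WT, with adjusted p = 0.611 and 0.447 in edgeR's quasi-likelihood test, and 0.30 ± 0.39 between the mutants (adjusted p = 0.9998). With 1 library left out these values ran from -0.49 to -0.09, -0.86 to -0.40 and 0.11 to 0.53. The values nearest 0 came without WT replicate 3 against WT, and without G313R replicate 1 between the mutants, and limma-voom gave -0.09 for V336Y. The differences between genotypes were within the spread between libraries. The counts do not tell the mutant from the wild-type transcript, and MRPS5 overlaps ZNF514 on the same strand.

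**Figure D1:**
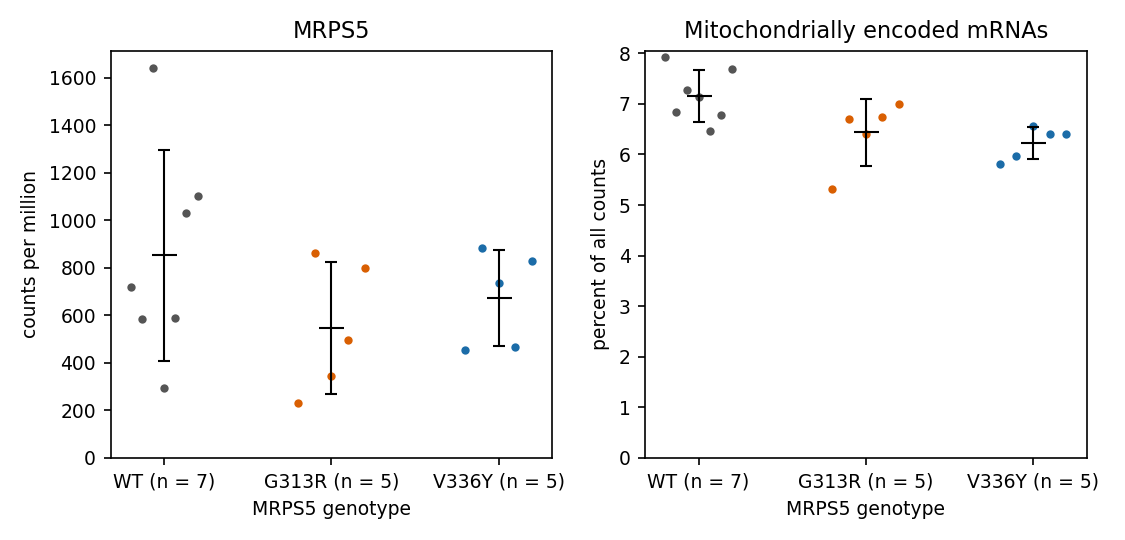
MRPS5 level in CPM (left) and the share of all counts on the 13 mitochondrially encoded mRNAs in percent (right), 1 point per library, with mean and SD as black bars for WT, G313R and V336Y. MRPS5 ranged from 230 to 1642 CPM, and the mitochondrial share had means of 7.16%, 6.43% and 6.23%.

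In V336Y cells 25 genes were higher and 28 lower than in WT. Of 14068 genes 3148 had an unadjusted p under 0.05 in edgeR's quasi-likelihood test, where chance gives 703, and 780 had an adjusted p under 0.1. The largest rises by the naming rule were FUOM, a fucose mutarotase (chromosome 10, 133355154 to 133358035; 13 ± 2.5 CPM in WT, 23.4 ± 2.43 CPM in V336Y, 1.81-fold), CCDC61 (1.77-fold), DNAAF3, an assembly factor of ciliary dynein arms (27 ± 3.3 to 42.5 ± 2.98 CPM, 1.58-fold), and FAAH, which hydrolyses fatty acid amides such as anandamide (1.54-fold). The largest fall by the naming rule was in MGST1, a membrane-bound glutathione transferase (chromosome 12, 16347142 to 16609259), from 9.99 ± 5.22 CPM in WT to 1.60 ± 1.26 CPM, a log2 fold change of -2.60 ± 0.51 (-3.24 to -2.39 with 1 library left out). Lower too were HMGCS1, the cytosolic synthase of hydroxymethylglutaryl-CoA in sterol synthesis (chromosome 5, 43289395 to 43313512; 242 ± 35 to 152 ± 19.7 CPM, log2 fold change -0.66 ± 0.14), and 4 KRAB zinc finger genes, ZNF140 (-0.81 ± 0.16), ZNF136 (-0.79 ± 0.15), ZNF268 (-0.56 ± 0.10) and ZNF468 (-0.52 ± 0.11).

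The other genes named by the rule rose by 0.48 to 0.56 on the log2 scale: TRIP6, an adaptor at focal adhesions, HPS6, a subunit of the BLOC-2 complex of lysosome-related organelles, ITPRIP, TMEM256, SERF2 and CCNDBP1. Those that were lower were KLHL15 (-0.81 ± 0.17), an adaptor of a cullin ubiquitin ligase, WNK3 (-0.67 ± 0.14), a kinase that regulates ion transport, SH2D4A (-0.52 ± 0.10) and CHML (-0.49 ± 0.10), a Rab escort protein. Several stood in chromosome regions whose level differed between libraries. SERF2 and CCNDBP1 lie on chromosome 15, where all 10 called genes were higher in V336Y and the median expressed gene was 0.20 (log2) above WT (exact permutation p = 0.00631, adjusted p = 0.110 over 23 chromosomes and 3 comparisons). In G313R the same median was 0.20 above WT (exact permutation p = 0.00758, adjusted p = 0.110). KLHL15 and WNK3 lie on the X chromosome, where the median gene was -0.15 against WT (exact permutation p = 0.00126, adjusted p = 0.0871), and FUOM, HPS6 and ITPRIP on chromosome 10, where it was 0.12 higher (exact permutation p = 0.0947, adjusted p = 0.436). CCDC61, DNAAF3, ZNF136 and ZNF468 lie on chromosome 19, where the median gene was 0.20 higher in V336Y (exact permutation p = 0.0682, adjusted p = 0.392). The chromosome 19 median was lowest in WT replicates 1, 2 and 7 (-0.56, -0.35 and -0.24). The 40 nearest other expressed genes carried a share of 0.322 of the fold change of CCDC61 and 0.381 of that of DNAAF3. The GC trends of the libraries predicted similar shares, 0.276 and 0.351, so the 2 are not told apart here. Of these genes CCDC61, DNAAF3, SERF2, CCNDBP1, ITPRIP, MGST1, ZNF140, WNK3, HMGCS1 and SH2D4A overlap a gene on the opposite strand, and CCDC61, DNAAF3, TRIP6, SERF2, CCNDBP1, TMEM256, MGST1, ZNF268, ZNF468 and CHML overlap 1 or more on the same strand, so their counts could be shared.

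**Figure D2:**
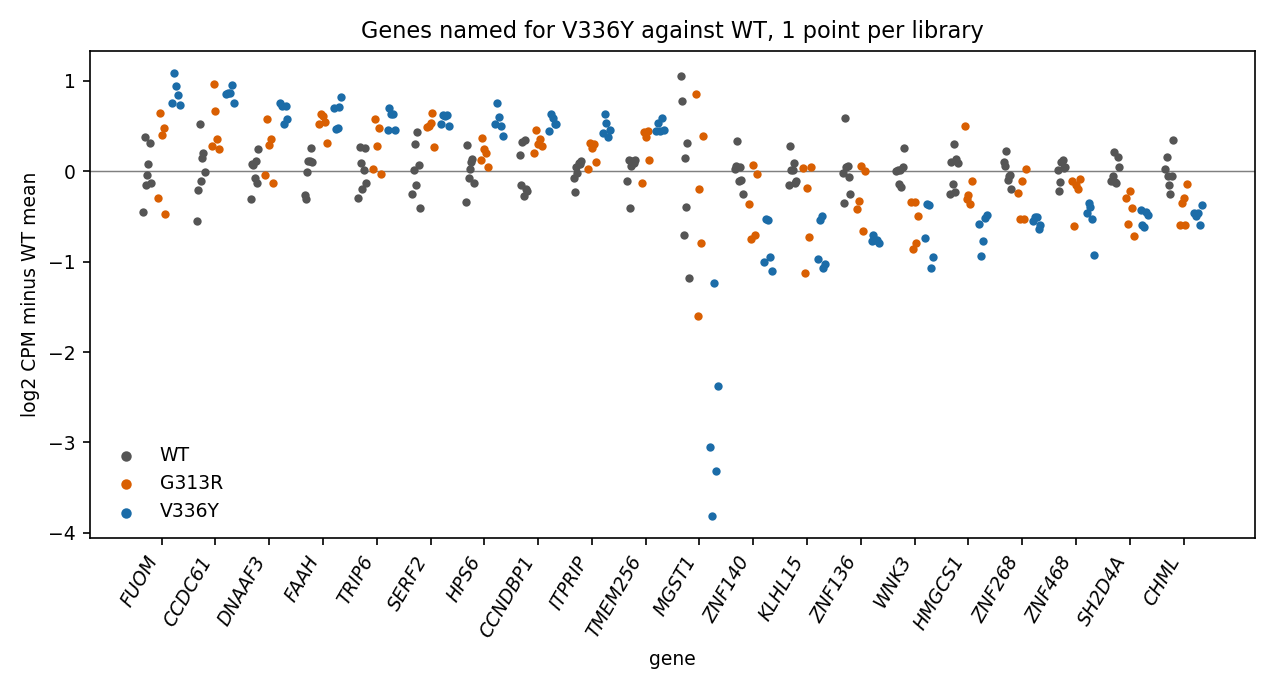
Log2 CPM relative to the mean of the WT libraries for the 20 genes named for V336Y against WT, 1 point per library, by genotype. Every V336Y library lies beyond every WT library for each gene, as the naming rule required, and the log2 fold changes run from -2.60 for MGST1 to 0.85 for FUOM.

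The adjusted p of these 20 genes lay between 0.0275 and 0.0499 in edgeR's quasi-likelihood test. All 5 V336Y libraries lay beyond the 7 WT libraries for these 20, as the naming rule required. Of the 53 called genes 44 were separated in this way, as were 4.04% of the genes tested (chance gives 0.253%). The V336Y libraries were unequally alike, with a chi-square of counts over its degrees of freedom of 5.62 between replicates 1 and 4, 9.44 between 1 and 5, 8.39 between 4 and 5, 10.4 between 2 and 3, and 38.3 to 48.5 for the other 6 pairs. Without any 1 of V336Y replicates 1 to 5, WT replicate 4 or WT replicate 6 no gene passed, without WT replicates 1, 2, 3, 5 and 7 the counts were 95, 43, 122, 210 and 16. With upper-quartile scaling 44 genes were called higher and 88 lower, and with the level of neighbouring genes removed 43 and 91. In that setting the calls of FUOM (0.70 ± 0.18), TMEM256 (0.39 ± 0.09) and HMGCS1 (-0.59 ± 0.15) were lost with fold changes within 1 SE of those above (adjusted p between 0.0512 and 0.0607). Those of DNAAF3 (0.40 ± 0.12), HPS6 (0.36 ± 0.09), ITPRIP (0.29 ± 0.09), SERF2 (0.26 ± 0.09), KLHL15 (-0.23 ± 0.09) and WNK3 (-0.17 ± 0.14) were lost with smaller ones. With the GC trends of the libraries removed 178 genes were called, without DNAAF3 (0.42 ± 0.11), FAAH (0.40 ± 0.12), TRIP6 (0.27 ± 0.09) and HPS6 (0.24 ± 0.09). Their adjusted p lay between 0.0534 and 0.145. DESeq2 called 902 genes, limma-voom 2729 and a test against a 1.2-fold change 0, with 1028 genes at an unadjusted p under 0.05. The quality weights of limma-voom were highest for V336Y replicates 5, 4 and 1 (3.61, 2.74 and 2.12), the libraries most alike. Those of V336Y replicates 2 and 3 were 0.632 and 0.754.

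The 13 mitochondrially encoded mRNAs, which encode subunits of the respiratory chain and ATP synthase, took 6.23 ± 0.323% of counts (SD, n = 5) against 7.16 ± 0.519% in WT (n = 7), a difference of -0.93 percentage points (exact two-sided permutation p = 0.00631, adjusted p = 0.0947 over the measures tested). Of the 13, 12 had a negative fold change. MT-ND3, a complex I subunit, fell from 963 ± 57.8 to 768 ± 59.5 CPM (log2 fold change -0.33 ± 0.06, edgeR adjusted p = 0.0450), and was the only 1 past the threshold over all genes; 7 passed when adjusted over the list alone. MT-CYB of complex III was at -0.33 ± 0.07 (adjusted p = 0.0528), MT-ND4 at -0.22 ± 0.06 and MT-ND5 at -0.31 ± 0.09. Camera called the list lower (adjusted p = 0.000142). With an estimated correlation the adjusted p = 0.810, with fry it was 0.107, and the exact permutation of the list mean gave p = 0.00379 (adjusted p = 0.0739).

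Cytosolic ribosomal protein mRNAs were called higher in V336Y (78 genes, 59 with a positive fold change, median log2 fold change 0.10, camera adjusted p = 1.35e-05; adjusted p = 0.810 with an estimated correlation). No member passed over all genes and 11 passed adjusted over the list alone. RPL28 was at 0.46 ± 0.11 and RPL18 at 0.34 ± 0.09, both on chromosome 19, where the median gene was 0.20 higher, and RPL4 on chromosome 15 at 0.24 ± 0.08. RPS4X on the X chromosome was at -0.13 ± 0.06. It was at 0.55 with the level of neighbouring genes removed. Immediate-early and serum response genes were called higher (24 genes, 18 positive, camera adjusted p = 0.00828; adjusted p = 0.810 with an estimated correlation and 0.0897 with the GC trends of the libraries removed). MYC rose from 586 ± 46.5 to 790 ± 79.9 CPM (log2 fold change 0.43 ± 0.09, edgeR adjusted p = 0.0450; 0.28 and adjusted p = 0.107 with the GC trends removed), and JUN was at 0.40 ± 0.10, JUNB at 0.92 ± 0.25 and KLF4 at 0.28 ± 0.09; 4 members passed adjusted over the list alone and 1 over all genes.

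Targets of the integrated stress response and its transcription factor ATF4 were called higher (37 genes, 31 positive, median log2 fold change 0.21, camera adjusted p = 0.000271). With an estimated correlation of 0.512 between members the adjusted p = 0.810, and the exact permutation p was 0.0758 (adjusted p = 0.227). No member passed over all genes and 1 passed adjusted over the list alone. CEBPB was at 0.52 ± 0.12, PCK2, the mitochondrial phosphoenolpyruvate carboxykinase, at 1.16 ± 0.41, CBS at 0.67 ± 0.29 and PPP1R15A at 0.25 ± 0.09, while ATF4 itself was at 0.11 ± 0.16 (0.06 to 0.17 with 1 library left out). With the level of neighbouring genes removed PPP1R15A was at -0.06 and ATF4 at -4.9e-05. Cholesterol biosynthesis genes were called lower (24 genes, 19 negative, camera adjusted p = 0.00106; adjusted p = 0.810 with an estimated correlation; exact permutation p = 0.0114, adjusted p = 0.111). HMGCS1 passed over all genes and 4 members passed adjusted over the list alone. FDFT1, squalene synthase, was at -0.24 ± 0.07, CYP51A1 at -0.21 ± 0.07 and MSMO1 at -0.33 ± 0.11. Camera called 8 lists in place of 5 without WT replicate 2 or V336Y replicate 2, and 9 without V336Y replicate 3.

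**Figure D3:**
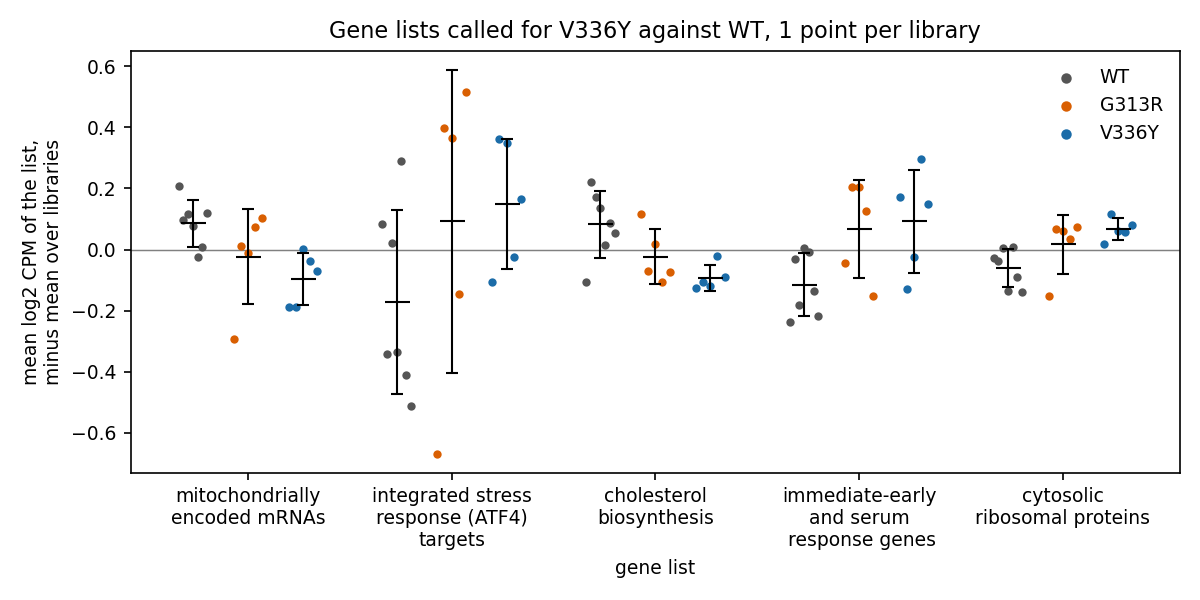
Mean log2 CPM of the 5 gene lists called by camera for V336Y against WT, minus the mean over the 17 libraries, 1 point per library, with mean and SD as black bars by genotype. The lists of mitochondrially encoded mRNAs and of cholesterol biosynthesis lie lower and the other 3 higher in V336Y, and libraries of the same genotype spread widely for the integrated stress response targets.

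In G313R cells no gene passed the threshold against WT in edgeR's quasi-likelihood test, with a smallest adjusted p of 0.0592. Of 14068 genes 1954 had an unadjusted p under 0.05, where chance gives 703, and 55 had an adjusted p under 0.1. DESeq2 called 180 genes and limma-voom with quality weights 0. Without WT replicates 1, 2 and 5 the test called 29, 1 and 65 genes, and without G313R replicate 3 it called 1. Among the lists, camera called 5 higher and 3 lower, and 5 in all without G313R replicate 4. With exact permutation of list means 0 lists passed, and the smallest adjusted p was 0.409. Targets of the integrated stress response were called higher (37 genes, 33 positive, median log2 fold change 0.19, camera adjusted p = 0.000117). With an estimated correlation the adjusted p = 0.715, and the exact permutation p was 0.264. The list mean, relative to that of all libraries, was -0.668 in G313R replicate 1, the lowest of 17 libraries, and -0.146 in replicate 4. It was 0.366 to 0.514 in G313R replicates 2, 3 and 5. CEBPB was at 0.52 ± 0.12, the amino acid transporters SLC7A5 at 0.49 ± 0.19 and SLC7A1 at 0.23 ± 0.08, and PPP1R15A at 0.29 ± 0.09. ATF4 was at 0.15 ± 0.16 (0.00022 without G313R replicate 5, 0.27 without G313R replicate 1) and EPRS at -0.01 ± 0.08. Immediate-early and serum response genes were called higher (24 genes, 19 positive, camera adjusted p = 0.00433; adjusted p = 0.641 with an estimated correlation), with MYC at 0.40 ± 0.09, JUNB at 0.86 ± 0.25 and JUN at 0.29 ± 0.10. Replication-dependent histones (23 genes, 21 positive, camera adjusted p = 0.00559) and cytosolic ribosomal proteins (78 genes, 53 positive, camera adjusted p = 0.00568) were called higher, both with an adjusted p = 0.715 with an estimated correlation. HIST1H2BK was at 0.37 ± 0.20 and HIST1H2AM, below 1 CPM, at 0.71 ± 0.32. RPL28 was at 0.37 ± 0.11 and RPL29 at 0.38 ± 0.12, while RPS4X was at -0.14 ± 0.06. It was at 0.33 with the level of neighbouring genes removed. Without G313R replicate 5 the calls of the integrated stress response and of the cytosolic ribosomal proteins were lost (camera adjusted p = 0.0643 and 0.0945). That of the ribosomal proteins was also lost with the level of neighbouring genes removed (0.139), and that of the histones with genes of at least 1 CPM in 5 libraries (0.156). The median gene of chromosome 19, which holds RPL28, was 0.20 higher in G313R (exact permutation p = 0.124, adjusted p = 0.454).

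The large subunit of the mitochondrial ribosome was also called higher in G313R (50 genes, 32 positive, median log2 fold change 0.04, camera adjusted p = 0.0334; adjusted p = 0.715 with an estimated correlation), with MRPL34 at 0.34 ± 0.09, MRPL58 at 0.25 ± 0.08 and MRPL52 at 0.29 ± 0.10. MRPL37 was at -0.01 ± 0.08. That call was lost without WT replicate 1, 3, 6 or 7 or G313R replicate 1 or 4 (camera adjusted p between 0.0513 and 0.218) and with the level of neighbouring genes removed (0.0621). With 1 library left out it was kept in 6 of 12 settings. Mitochondrially encoded mRNAs were called lower (10 of 13 negative, camera adjusted p = 0.0177; adjusted p = 0.715 with an estimated correlation), with MT-CYB at -0.21 ± 0.07, MT-ATP6 at -0.17 ± 0.07 and MT-CO2 at -0.20 ± 0.09. This call was lost without WT replicate 1 or G313R replicate 1 (camera adjusted p = 0.0794 and 0.406; MT-ATP6 at -0.09 and MT-CO2 at -0.12 without the latter) and with the GC trends removed (0.111). They took 6.43 ± 0.658% of counts (n = 5), a difference from WT of -0.72 percentage points (exact permutation p = 0.0543, adjusted p = 0.271); without WT replicate 5 or G313R replicate 5 the exact permutation p was 0.0195 or 0.0333, and without G313R replicate 1 the difference was -0.445 points (exact permutation p = 0.148). Extracellular matrix and adhesion genes (31 genes, 21 negative, camera adjusted p = 0.0333) and hypoxia-responsive genes (20 genes, 16 negative, camera adjusted p = 0.0380) were called lower, both with an adjusted p = 0.715 with an estimated correlation. The laminin chain LAMA1 was at -0.62 ± 0.15, the collagen chain COL5A1 at -2.21 ± 0.59 and MMP2 at -1.69 ± 0.45, and 4 members were lower and 1 higher adjusted over the list alone. TNC was at 0.71 ± 0.65. PDK1 was at -0.40 ± 0.15 and AK4 at -0.20 ± 0.08. ERO1A was at 0.14 ± 0.11 (0.06 without WT replicate 3) and NDRG1 at -0.46 ± 0.36 (0.15 with DESeq2, 0.16 without WT replicate 3). The hypoxia call was lost without WT replicate 1, 3 or 7 or G313R replicate 2, 3 or 4 (camera adjusted p between 0.0513 and 0.123), and was kept in the other 6 of 12 settings. It was lost too with the GC trends (0.111) or the level of neighbouring genes (0.139) removed. The extracellular matrix call was lost without WT replicate 6 or G313R replicate 1 or 4 (0.0716 to 0.130) and with the level of neighbouring genes removed (0.0905). No member of these 8 lists passed over all genes. Adjusted over the list alone, 1 integrated stress response target and 2 immediate-early genes were higher, and 0 members passed in the other lists besides the extracellular matrix.

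Between V336Y and G313R no gene passed in edgeR's quasi-likelihood test, with 587 genes at an unadjusted p under 0.05, fewer than the 703 that chance gives, while DESeq2 called 2 and limma-voom 0. Camera called fatty acid beta-oxidation genes higher in V336Y (19 genes, 15 positive, median log2 fold change 0.11, adjusted p = 0.000396; adjusted p = 0.0796 with an estimated correlation; exact permutation p = 0.00794, the smallest it can give, adjusted p = 0.310). The carnitine palmitoyltransferases CPT1A and CPT1C were at 0.42 ± 0.14 and 0.59 ± 0.23, DECR1 at 1.09 ± 0.46 (1.70 without G313R replicate 2) and ECHS1 at 0.27 ± 0.10. ETFA was at -0.05 ± 0.08. Cytosolic ribosomal proteins (65 of 78 positive) and p53 targets (16 of 20 positive) were called higher, each at camera adjusted p = 0.00829, and mitochondrially encoded mRNAs (11 of 13 negative, adjusted p = 0.0257) and cholesterol biosynthesis genes (19 of 24 negative, adjusted p = 0.0360) lower, all 4 with an adjusted p = 0.942 with an estimated correlation. The death receptor FAS was at 0.42 ± 0.15, HMGCS1 at -0.58 ± 0.15 and MT-ND3 at -0.19 ± 0.07. MDM2 was at 0.01 ± 0.11, PMVK at 0.28 ± 0.12, FDPS at 0.02 ± 0.06 and MT-CO1 at -0.01 ± 0.11. Over all genes 0 members of these 5 lists passed, and adjusted over the list alone 1 did, in cholesterol biosynthesis. Camera called 3 lists without V336Y replicate 1 or 5 and 2 without V336Y replicate 2. The call of the mitochondrially encoded mRNAs was lost without G313R replicate 2, 4 or 5 or V336Y replicate 1 or 2 (camera adjusted p between 0.142 and 0.252) and with the GC trends removed (0.184). That of cholesterol biosynthesis was lost without G313R replicate 1 or V336Y replicate 1, 2, 3 or 5 (0.0561 to 0.593). With 1 library left out each was kept in 5 of 10 settings. The p53 call was lost without G313R replicate 1 or V336Y replicate 5 (0.446 and 0.153). That of the cytosolic ribosomal proteins was lost without G313R replicate 1 or V336Y replicate 2 (0.912 and 0.119). The mitochondrial share of counts differed by -0.21 percentage points (exact permutation p = 0.563), and without G313R replicate 1 by -0.49 (exact permutation p = 0.0476).

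The fold changes of the 2 mutants against WT were correlated. Across 14068 genes the log2 fold changes of V336Y and G313R against WT had Pearson r = 0.759, and 78.4% had the same sign. Simulated data, with all 17 libraries drawn independently and without any genotype effect, gave r = 0.414 and 63.7%. Such draws lack the likeness between some of the real libraries. Relabelling the real libraries gave a median r of 0.447 and at most 0.764. The covariance was 0.0870 against a simulated 0.0176, a difference of 0.0695. With the WT libraries divided so that the mutants shared none, r was 0.370 to 0.648 and the covariance 0.0508 to 0.0790 over 70 divisions. No gene was called in both mutants, since none was called in G313R. On the first principal component of all 17 libraries (28.9% of variance) G313R replicates 2 and 4 were at 27.7 and 39.98, V336Y replicates 1, 4 and 5 at 36.3, 36.5 and 31.8, and the other 12 libraries between -26.1 and -1.50. The library nearest by correlation was V336Y replicate 5 for G313R replicate 2 and V336Y replicate 1 for G313R replicate 4. Dividing the WT libraries leaves this likeness between libraries of the 2 mutants in place. The correlation therefore does not tell a shared effect of the substitutions from that likeness.

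**Figure D4:**
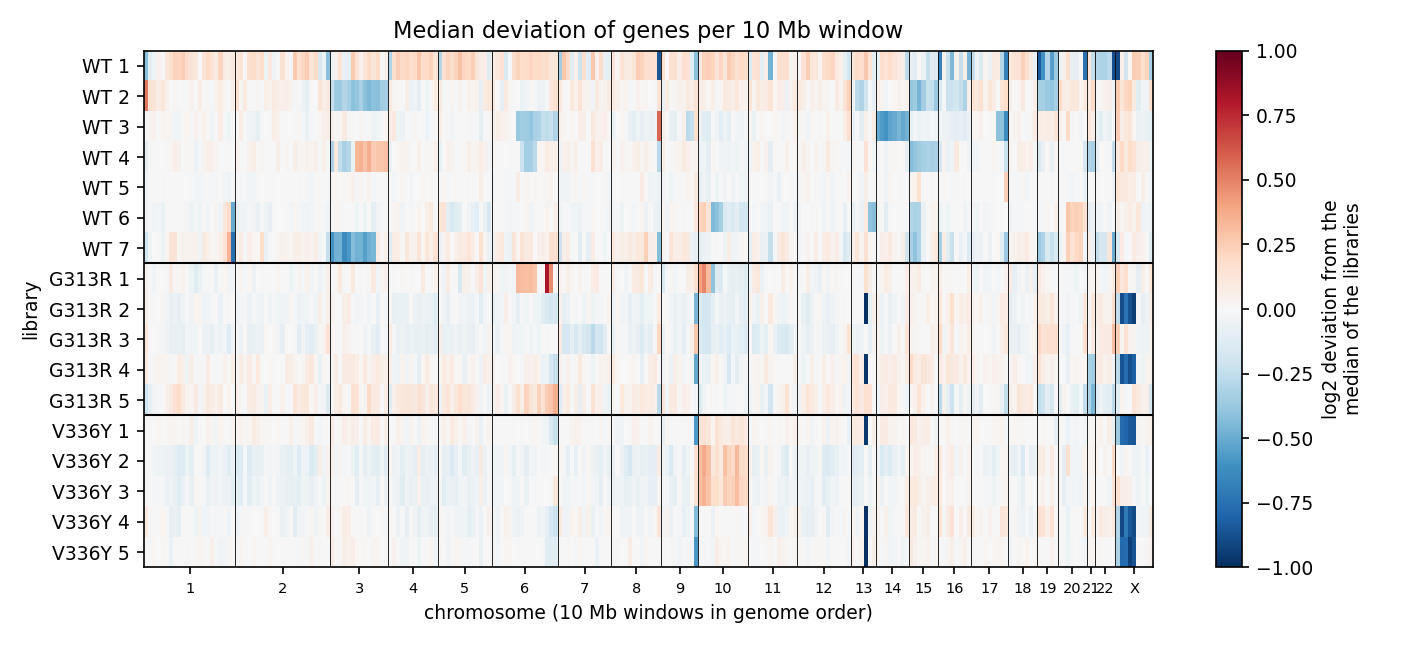
Median log2 deviation of genes from their median over libraries, in 244 windows of 10 Mb in genome order (horizontal axis), for the 17 libraries (vertical axis, black lines between genotypes), with blue lower and red higher. Blocks of windows differ between single libraries, such as chromosome 14 in WT replicate 3 (chromosome median -0.51) and part of the X chromosome in G313R replicates 2 and 4 and V336Y replicates 1, 4 and 5.

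Whole blocks of chromosomes stood apart in single libraries. In the window from 50000001 to 60000000 of the X chromosome (23 genes) the median deviation was -0.87 in G313R replicate 2, -0.88 in G313R replicate 4, -0.84 in V336Y replicate 1, -0.85 in V336Y replicate 4 and -0.93 in V336Y replicate 5, and between 0 and 0.23 in the other 12 libraries. In the window from 70000001 to 80000000 of chromosome 13 (21 genes) the same 5 libraries lay between -1.11 and -0.96, and the others between -0.18 and 0.27. The median gene of chromosome 3 was at -0.36 in WT replicate 2 and -0.47 in WT replicate 7, that of chromosome 15 at -0.32 in WT replicate 2, -0.35 in WT replicate 4 and -0.20 in WT replicate 7, and that of chromosome 10 at 0.25 in V336Y replicate 2 and 0.24 in V336Y replicate 3. The exact permutation p of the X chromosome in V336Y against WT was the smallest that 792 arrangements can give, and a chromosome alone at that value reaches no adjusted p below 0.0871.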

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

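The tests of regions and GC content were chosen after the results were seen, and the counts of other splits and the tests on MRPS5 before. Of 108 groups of per-library values examined for a library far from its group, 4 stood out, and chance gives about 5.4. WT replicate 7 had 21240434 counts against 36349345 in the next lowest WT library. G313R replicate 1 had the lowest mean log2 level of the mitochondrially encoded mRNAs in its group (-0.291 against -0.011 for the nearest, relative to the mean of all libraries) and of the cytosolic ribosomal proteins (-0.152 against 0.034). ZNF468 was at 3.66 log2 CPM in G313R replicate 2 against 4.07 in the nearest G313R library.

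Chance can be excluded for the 53 genes called between V336Y and WT only if the libraries are independent: 1 of 100 splits of these 12 libraries, the real one, gave as many, and the highest of the others gave 1. The labels do not say whether they are, V336Y replicates 1, 4 and 5 and replicates 2 and 3 were closer to each other than the other pairs (chi-square of counts over its degrees of freedom of 5.62 to 10.4 against 38.3 to 48.5), and without any 1 V336Y library 0 genes were called. For G313R against WT and V336Y against G313R the real counts were 0, so that all 100 of 100 splits give as many by construction (highest other 1 in each) and these splits say nothing about chance. For the gene lists at the preset correlation, 48 of 100 splits gave 5 or more lists for V336Y against WT (highest other 20), 27 of 100 gave 8 or more for G313R against WT (highest other 17), and 56 of 100 gave 5 or more for V336Y against G313R (highest other 23), so chance cannot be excluded for these counts of lists. Whether the splits with several times the real number reflect a structure of the libraries other than genotype stays open, since the correlation estimated between members, such as 0.430 for the mitochondrially encoded mRNAs and 0.512 for the integrated stress response targets in V336Y against WT, lay above the preset 0.01. Of 100 labellings of the 17 libraries, 2 gave a correlation between the mutants' fold changes as high as the real one, which were the real one (0.758 in this fit) and 1 other (0.764; median of the others 0.447).

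The V336Y calls were concentrated on chromosome 15, with 10 of 53 genes against 1.78 expected (Fisher's exact p = 8.93e-06, adjusted p = 0.000214 over 24 chromosomes; neighbouring genes are not independent). On chromosome 15 the 40 nearest other expressed genes carried a median share of 0.638 ± 0.067 (bootstrap SE) of the fold change of the called genes. The SE of this and the shares below were taken over genes, which share libraries and partly neighbours, and leave out the spread between libraries. A shift of the whole region would give such a share. All 7 WT libraries lay below all 10 mutant libraries on chromosome 15 (chromosome medians of -0.352 to 0.0152 against 0.0197 to 0.0926). On other nuclear chromosomes that share was 0.0440 ± 0.017 for the 26 genes called lower. That argues against a shift of the wider region as their cause, apart from KLHL15 and WNK3 on the X chromosome. Those were the only 2 with a share of 0.5 or more. A shift of only a few adjacent genes would not show in a median of 40. ZNF140 and ZNF268, both called lower, start at 133079838 and 133181409 on chromosome 12. For the 15 called higher the share was 0.217 ± 0.075, and 7 of them kept their call with the neighbour offset. That leaves a regional shift open as a part of the cause for the 15. The GC trend of the libraries predicted a median share of 0.0615 ± 0.011 over the genes called lower, which argues against it as their cause, and 0.202 ± 0.097 over those called higher, of which 16 of 25 kept their call with the GC offset, so that it is argued against as the whole cause of those 16 and stays open as a part of it, and for the other 9, among them HPS6 (0.561) and TRIP6 (0.522). Whether the calls outside these regions follow from the V336Y substitution or from the history of the cultures stays open. The labels name no clones. V336Y replicates 1, 4 and 5 stood with G313R replicates 2 and 4 on the first principal component, apart from every WT library. The comparisons with WT are therefore partly confounded with that likeness. No term for it was fitted as such, and what the 1 surrogate variable captured was not examined.

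The regional blocks differed between libraries of 1 genotype. Of 244 windows, 53 lay 0.4 or more (log2) away in at least 1 library, and in 0% of these did all libraries of a genotype lie beyond all others, which argues against genotype as the cause of these windows as a set, while for the level of chromosome 15 it stays open. Adjacent windows lay on the same side in 82.5% of cases against at most 28.6% in 1000 shuffles of window order, as blocks shifted together would give, so gains and losses of chromosome segments between cultures may be the cause; no DNA was measured. After the GC trends were removed 73.0% of the window and library pairs remained, which leaves open that GC content accounts for part of them.

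The 7.15-fold range of MRPS5 between libraries had no counterpart in its surroundings. The 40 nearest other expressed genes varied by 4.66% of the MRPS5 range on the log2 scale, and counting error was at most 1.19% of the count. A shift of the wider region and counting error are therefore argued against. The overlapping gene ZNF514 reached at most 7.52% of the MRPS5 level. That counts only reads assigned to ZNF514, and the treatment of reads shared between genes is not known. It therefore cannot decide whether shared reads contributed. Over the 17 libraries MRPS5 CPM and total counts had Spearman rho = 0.306 (permutation p = 0.230) and Pearson r = 0.209 (permutation p = 0.412), and r = 0.536 without the 2 libraries with totals farthest from the median. That MRPS5 was expressed from an added copy whose level differed between cultures may explain both the height and the range, and was not tested, as the labels do not describe how the genotypes were made.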

How the results depend on the processing

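The GC, neighbour and robust-dispersion settings and the permutation of list means were chosen after seeing the data. The cause was not tested for any value below. No paired analysis was possible because the labels number no replicates, and the library numbers in the titles are shared by no samples. For V336Y against WT, 53 genes became 132 with upper-quartile factors, 14 without a filter on low counts, 0 at a fold threshold of 1.2, 327 with 1 surrogate variable, 178 with the GC offset, 134 with the neighbour offset (43 higher, 91 lower), 187 with only the compared groups, 902 with DESeq2, 2729 with limma-voom quality weights and 0 with WT replicates 1 to 5 only; leaving out 1 library gave 0 to 210. With the neighbour offset 32 of the 53 genes were shared. All 20 named genes kept their sign in every setting, which their selection for full separation of V336Y from WT made likely. Of the 20, 11 stayed past the threshold with the neighbour offset and 16 with the GC offset. For G313R against WT, 0 became 21 with the GC offset and 180 with DESeq2, and 0 to 65 with 1 library left out. For V336Y against G313R, 0 became 2 with DESeq2, and 0 to 0 with 1 library left out. MRPS5 passed no threshold in any setting.

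The called lists became 0 in all 3 comparisons with an estimated correlation, with fry and with exact permutation, though for V336Y against G313R a list alone at the smallest permutation p, 0.00794, reaches only an adjusted p of 0.310. For V336Y against WT, 5 became 10 with the GC offset and 5 to 9 with 1 library left out. The other ranges were 5 to 10 for G313R against WT and 2 to 7 for V336Y against G313R. Of the 5, 8 and 5 called lists the GC offset kept 4, 6 and 4 and the neighbour offset 5, 4 and 5. The mitochondrial share differed by -1.05 to -0.803, -0.865 to -0.445 and -0.486 to -0.0658 points in the 3 comparisons with 1 library left out, and r between the mutants was 0.746 to 0.783.

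Signs turned for the genes below, none of which had passed the threshold over all genes. In G313R against WT, MRPL37 was at 0.0011 with RLE, 0.0027 without a filter, 0.033 with the neighbour offset, 0.00093 with DESeq2 and 0.029 with limma-voom (left out: -0.042 to 0.061). EPRS was at 0.019 with the GC offset, 0.038 with the neighbour offset and 0.039 without G313R replicate 1 (-0.052 to 0.040). NDRG1 was at 0.145 with DESeq2 and 0.0030 with limma-voom (-0.588 to 0.158). With the neighbour offset RPS4X was at 0.334 and RPL4 at -0.0054. In V336Y against WT the neighbour offset put PPP1R15A at -0.056, ATF4 at -4.9e-05 and RPS4X at 0.549. In V336Y against G313R, MT-CO1 was at 0.0066 with upper quartile, 0.010 with library totals and 0.011 with the GC offset (-0.072 to 0.019), FDPS at -0.0049 with the GC and -0.014 with the neighbour offset (-0.0058 to 0.057), and RPS24 at -0.023 with the neighbour offset. ETFA was at 0.013 and MDM2 at -0.035 without G313R replicate 1 (-0.095 to 0.013 and -0.050 to 0.063), and RPS4X at -0.028 with limma-voom (-0.029 to 0.046).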

Other observations

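HERC5, IFI44L and SP110, called lower in V336Y, lie outside the naming rule and were chosen after their values were seen. Of the 3 only IFI44L is in the list of interferon-stimulated genes, and no enrichment of such genes among the 53 called was tested. HERC5, an interferon-induced ubiquitin-like ligase, was at 29.2 ± 5.79 CPM in WT, 16.9 ± 1.56 in G313R and 17 ± 1.6 in V336Y, with log2 fold changes of -0.79 (edgeR adjusted p = 0.0592) and -0.78 (adjusted p = 0.0275). IFI44L was at 1.53 ± 0.745, 0.562 ± 0.379 and 0.374 ± 0.062 CPM, and SP110 at 4.55 ± 2.47, 2.80 ± 2.19 and 0.403 ± 0.203 CPM. The list of interferon-stimulated genes as a whole was not called (camera adjusted p = 0.377 for V336Y and 0.134 for G313R against WT), and 8 of its 20 members had a positive fold change in V336Y, among them ISG15 at 0.59 (edgeR adjusted p = 0.2004). Adjusted over the list alone, 2 members were lower and 0 higher in V336Y. Fry's mixed test, which counts changes in either direction and ignores genes outside the list, gave adjusted p = 0.000808 for V336Y and 0.0153 for G313R. Passing this test was not particular to interferon-stimulated genes. In V336Y it gave 0.00357 for cell proliferation and 0.00497 for neuronal genes, and in G313R 0.0153 for neuronal genes.

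The lists of nuclear genes of the respiratory chain and of mitochondrial quality control were not called. For V336Y against WT, camera gave adjusted p = 0.13 for nuclear complex I subunits (median log2 fold change 0.03), 0.582 for complex IV, 0.982 for ATP synthase, 0.340 for the small and 0.0508 for the large subunit of the mitochondrial ribosome, 0.126 for mitochondrial chaperones and proteases and 0.944 for the unfolded protein response of the endoplasmic reticulum. Serine and one-carbon metabolism, which shares regulators with the integrated stress response, had adjusted p = 0.232. Fry's mixed test gave adjusted p = 0.185 for ATP synthase and 0.109 for serine and one-carbon metabolism, and 0.0176 to 0.0364 for the others. Lists unrelated to mitochondria passed it too, such as neuronal genes (0.00497) and kidney developmental genes (0.0364), so these values single out no pathway.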
